A study of Homo sapiens with 4 samples.

How the data were processed

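RNA of the nasopharyngeal carcinoma cell lines HK1 and HK1EBV was measured after 24 h with 110 µM CAPE or 0.1% DMSO, on 1 array for each of the 4 groups. Per the labels' protocols, total RNA was purified with a column kit and a DNase step, and biotin-labelled cDNA was made from 250 ng of it with the Affymetrix WT PLUS kit for single-colour arrays. Per the submitters' processing notes the values were made by RMA, which corrects background, sets all arrays to one distribution and summarises the probes of a probe set. The deposited values were taken as log2 values because RMA gives that scale. The base of the log, a shift of the scale towards 0, any later centring, the version of RMA and the probe sets left out beforehand are not given in the sources used here. The values ran from -0.19 to 11.9, so differences between arrays were used and not levels between genes. The array medians were 2.25 for HK1 DMSO, 2.27 for HK1 CAPE, 2.25 for HK1EBV DMSO and 2.23 for HK1EBV CAPE. Across probe sets, arrays of the 2 treatments correlated at r = 0.991 within each line, and arrays of the 2 lines at 0.989 with DMSO and 0.988 with CAPE.

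Of 25800 probe sets, 18612 had 1 gene symbol in the platform annotation, 954 several and 6234 none. Only those with 1 symbol were used, and 18583 were matched by Entrez number to a RefSeq gene table of assembly GRCh38.p14, which changed 0 symbols. That table served for names, chromosomes and the order of genes, and no coordinates are given, since no build is named for the values. For a gene with several probe sets the one with the highest mean was taken, which gave 18323 genes. Genes were tested when that mean reached the 25th percentile of all probe sets, a log2 value of 0.997, which left 15194. Among the probe sets 217 had one value on all 4 arrays and 2643 a repeated value, the latter with a median level of 0.882. HSPA1A, among the preset genes, had no probe set of a single symbol and was not analysed here, and 1 other preset gene is not reported here.

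Gene-wise tests used limma 3.58.1 in R 4.3.3 (lmFit and eBayes) on all 4 arrays, with cell line and treatment as terms and 1 residual degree of freedom. The residual of that fit is the difference between the lines in the CAPE change together with array noise. Tests were two-sided, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05 on the adjusted p. Each SE given is the moderated SE of limma, in which a gene's variance is drawn towards a prior from all genes. Differences within 1 line or 1 treatment, and the difference between the lines in the CAPE change, had no residual degree of freedom and were given as values, with counts of genes at least 2-fold apart. Overlaps of such counts are set beside the number that independent lists of the same sizes would share. The correlation between the lines was taken across genes, with no p-value.

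The gene lists were 29 in number. They covered NRF2, heat shock, endoplasmic reticulum stress, ATF4, NF-κB, p53, aryl hydrocarbon receptor, hypoxia, metallothionein, immediate early, interferon and antigen presentation genes. They also covered G1/S, G2/M, homologous recombination, cholesterol synthesis, ribosome biogenesis, oxidative phosphorylation, autophagy, histone, apoptosis, epithelial, mesenchymal, metalloproteinase, squamous and basal keratinocyte genes, and fibroblast, leukocyte and endothelial markers. Each list with at least 5 genes tested was compared with all other genes by camera with a correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. An estimated correlation and fry were alternatives, and both rest on the 1 residual degree of freedom of the fit. Within each line or treatment, a list's median was placed among 10000 random lists of the same size, matched in 20 bins of mean level. Counts of list members are given over all genes tested and adjusted over the list alone.

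The groups, tests, lists, thresholds and the rule for named genes were fixed before the data were examined. For CAPE the rule took genes past the threshold with one sign in both lines, the 12 highest and 12 lowest by the smaller of the 2 differences. As only 1 passed, the others came from all genes tested by the same ranking. For the line difference it took the 10 highest and 10 lowest of those that passed, for the difference in CAPE change the 6 highest and 6 lowest, and for each list up to 4 members with the largest mean difference, besides 24 preset genes. HSPB1, LAMP1 and TIMP4 are among these list members. Genes of the Y chromosome and XIST were left out. The alternatives were no filter and a filter at the 50th percentile, arrays shifted to one median, quantile normalization, the mean of a gene's probe sets, a variance prior with a trend or a robust one, no block, and other thresholds of p and fold. Alternatives without genes of zero residual, without chromosomes 13 and 18 and without single list members were chosen after seeing the data. No array could be left out, since each group had 1.

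Neighbouring genes were examined by the median over windows of 9 genes, against 1000 permuted gene orders. The genes at the ends of the stretches, and those listed within a stretch of chromosome 6, were named after their values were seen. The scripts were tested on simulated data. In the CAPE comparison over 15194 genes, 83 of 100 genes changed by a log2 of 1 and 98 of 100 changed by 2 were recovered, with 21 false calls. In the line comparison these were 81 and 100 of 100, with 19 false calls. In both comparisons the false calls were a larger share of the calls than the threshold of 0.05. The simulation held no repeated values. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.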

Results

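RNA of the nasopharyngeal carcinoma cell lines HK1 and HK1EBV was measured on 4 single-colour arrays, 1 for each of 4 groups. Cells had been kept for 24 h with caffeic acid phenethyl ester (CAPE) at 110 µM or with dimethyl sulfoxide (DMSO) at 0.1% as control. CAPE is a component of propolis, known as an inhibitor of NF-κB signalling. HK1EBV was taken from its name as HK1 cells carrying Epstein-Barr virus. The labels name both lines as derived from this carcinoma and say no more of the virus. After the filter on dim probe sets 15194 genes were tested. The array medians lay between 2.23 and 2.27 on the log2 scale, and 4 arrays limit the precision of every value. No group had a replicate, so a difference within 1 line or 1 treatment had no replicate check. The lines served as the replicates of the CAPE effect, and the treatments as those of the line difference. Nothing in the labels says that the arrays came from separate cultures or days, so p-values of the gene-wise tests measured the spread between these arrays. Differences below are in log2 units.

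The first comparison asked which RNAs differed after CAPE in both lines. CYP1B1, a cytochrome P450 induced through the aryl hydrocarbon receptor, fell in both lines, with differences of -3.07 in HK1 and -2.80 in HK1EBV. Its mean change was -2.93 ± 0.12 (moderated SE of limma, n = 2 lines), or 7.65-fold. It was the 1 gene to pass (limma with Benjamini-Hochberg adjustment, adjusted p = 0.0471). The aldo-keto reductases AKR1C3, AKR1C1 and AKR1C2 were higher by 2.03, 1.81 and 1.69 in HK1 and by 1.99, 1.97 and 1.63 in HK1EBV. These paralogs are close in sequence, and a dimmer probe set of AKR1C1 gave 0.35 and 0.45, so the share of each is uncertain. ALDH1A3, a retinaldehyde dehydrogenase, differed by -2.31 in HK1 and by -2.90 in HK1EBV.

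The other genes named for CAPE, taken by the rule for a change in one direction in both lines, did not pass. P4HA1, a prolyl hydroxylase subunit of collagen synthesis, was higher by 1.63 ± 0.12 (moderated SE, n = 2), and AMTN by 1.68 ± 0.11. DDIT3, a transcription factor of the stress response, was higher by 1.39 in HK1 and 2.40 in HK1EBV. NMRAL2P, SMIM14, LURAP1L, CYP4F11, DUSP10 and CPEB2 were higher by 1.90, 1.64, 1.63, 1.45, 1.32 and 1.29 on average. Of the genes of ribosome assembly, UTP20 differed by -1.55, RRS1 by -1.52 and ESF1 by -1.51. The mitotic genes CENPF and ASPM differed by -1.48 and -1.31, and the linker histone gene H1-1, one of a family of similar copies, by -2.31. OTUB2, PIGW, PADI3 and GEMIN5 differed by -1.52, -1.50, -1.50 and -1.31. The adjusted p of these 23 genes lay between 0.0544 and 0.0704 in the limma test with Benjamini-Hochberg adjustment.

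**Figure D1:**
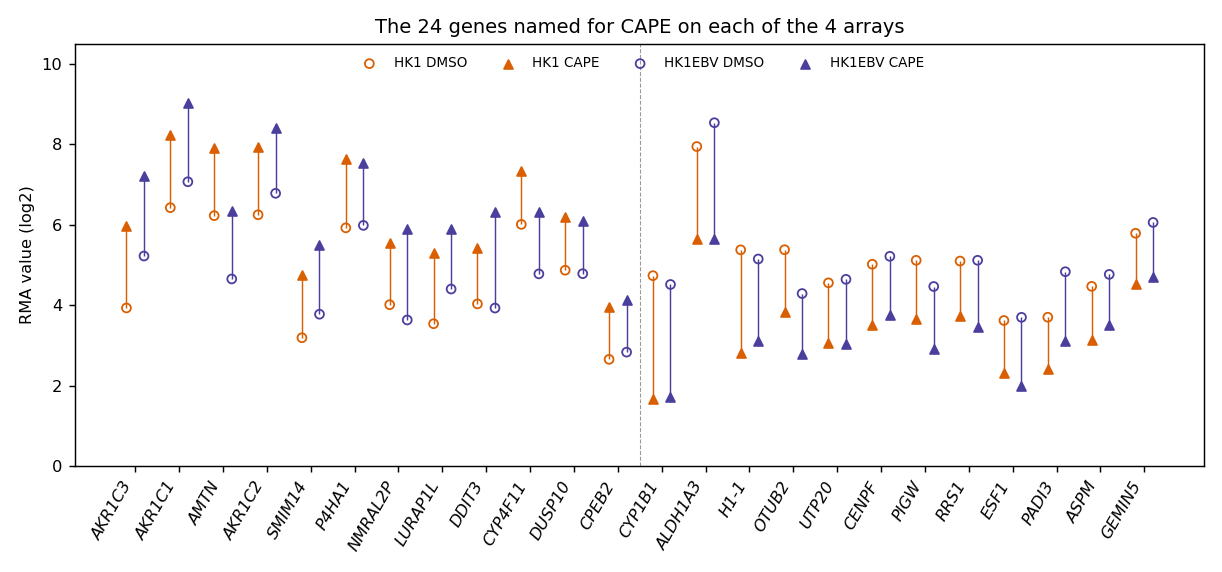
RMA values (log2, y axis) of the 24 genes named for CAPE on the 4 arrays, with circles for DMSO, triangles for CAPE and a line joining the 2 arrays of each cell line. CYP1B1, right of the dashed line, differs by -3.07 in HK1 and -2.80 in HK1EBV. Each gene moves the same way in both lines because the naming rule required it.

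The count of 1 gene, with 2968 at an unadjusted p under 0.05, depended on the setting, and CYP1B1 no longer passed without the filter on dim probe sets (limma adjusted p = 0.193) or without the cell line as a block (0.245, the range over alternatives being 4.16e-06 to 0.245), which left 0 genes. Leaving out 57 genes whose residual was exactly 0, a choice made after seeing the data, gave 1243 genes, 616 higher and 627 lower. All 24 named genes were among them, which the naming rule favoured, since it took large changes in both lines of these same arrays.

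The size of the CAPE change was also counted line by line, without a test. In HK1, 102 genes were at least 2-fold higher and 104 at least 2-fold lower, and in HK1EBV 105 and 81. Both lines shared 41 genes higher and 31 lower, against 0.705 and 0.554 for independent lists of these sizes. No gene (0) was 2-fold higher in one line and 2-fold lower in the other. Across genes, which are not independent replicates, the changes in both lines correlated at Pearson's r = 0.549 (Spearman's rho = 0.442). The mean CAPE change took 38.5% of the variance between arrays, the mean difference between the lines 50.3%, and the difference between the lines in the CAPE change 11.2%.

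**Figure D2:**
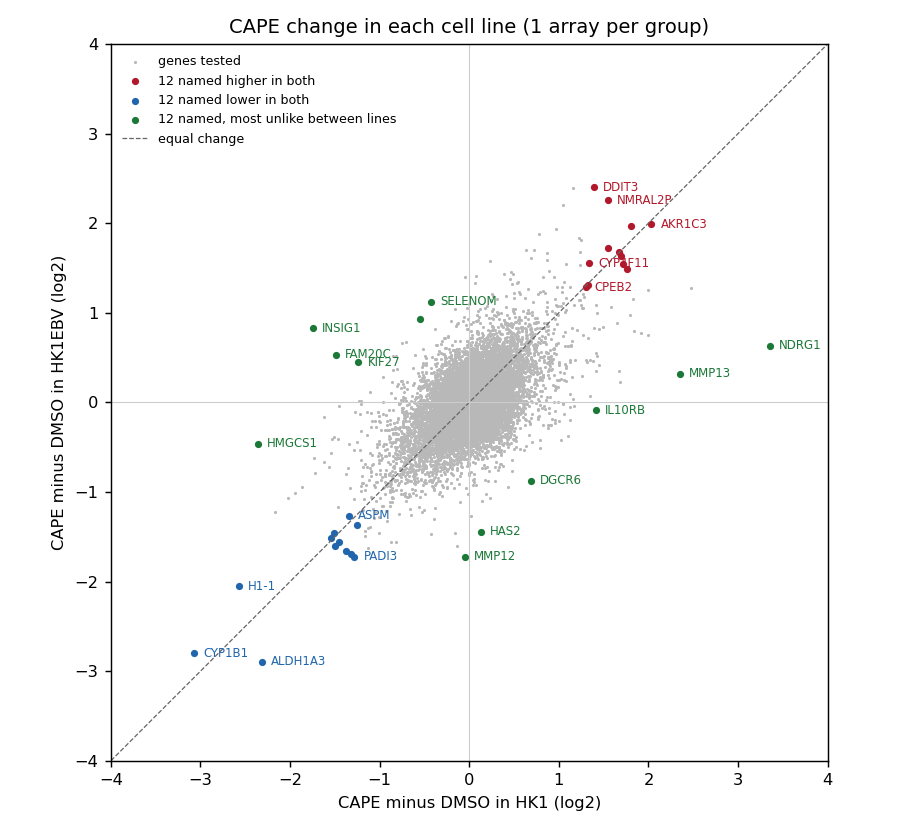
CAPE minus DMSO in HK1 (x axis, log2) against HK1EBV (y axis, log2) for 15194 genes, 1 array per group. Red and blue points are the 12 genes named as higher and the 12 named as lower in both lines, such as CYP1B1 at -3.07 and -2.80, and green points are the 12 with the most unlike changes, such as NDRG1 at 3.36 and 0.63.

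The gene lists fixed before the data were examined were compared with all other genes by camera with a preset correlation of 0.01. Its p rests on the spread across genes, taken as nearly uncorrelated, and not on replicate arrays. Members that move together can thus make it too small, here and below. Of 29 lists, 8 were higher and 9 lower with CAPE at an adjusted p under 0.05. None (0) passed with a correlation estimated from the residuals, at an adjusted p = 0.521 with an estimated correlation for 16 of these lists and 0.585 for cholesterol synthesis. By fry, which tests whether the genes of a list move on balance one way, none (0) passed, and the lowest adjusted p was 0.0983. Both alternatives rest on the 1 residual degree of freedom of the fit, so hardly any list could have passed. Their adjusted p values here and below thus say little for or against a list. In 13 of the 17 lists the median lay outside the middle 95% of random lists in both lines. In the counts of list members below, only CYP1B1 passed over all genes tested with the planned setting. Without the 57 genes of zero residual, a choice made after seeing the data, members that passed over all genes were 23 lower for ribosome biogenesis, 19 lower for G2/M, 10 lower for histones and 8 lower for G1/S. They were 15 higher for hypoxia, 14 for NRF2, 10 for endoplasmic reticulum chaperones, 10 for autophagy, 14 higher and 1 lower for ATF4, and 6 higher and 1 lower for NF-κB. Homologous recombination had 3 lower, cholesterol synthesis 2 lower, aryl hydrocarbon receptor targets 2 lower, metallothioneins 2 higher, antigen presentation 2 higher, heat shock 1 higher and 3 lower and oxidative phosphorylation 0. Of all 15137 genes in that fit 1243 passed for CAPE, so small counts here and below may be no more than that share.

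Genes of ribosome biogenesis were lower in both lines, with list medians of -0.69 in HK1 and -0.81 in HK1EBV (camera adjusted p = 1.67e-23, or 0.521 with an estimated correlation). Of 29 members, 28 fell when adjusted over the list alone, and 0 passed over all genes, or 23 without the genes of zero residual. Among them were DKC1, the pseudouridine synthase, at -1.07 and -1.29, and POLR1B, a subunit of RNA polymerase I, at -1.17 and -1.08. The list of G2/M and mitosis had medians of -0.49 and -0.43 (camera adjusted p = 1.96e-18, or 0.521 with an estimated correlation), and 24 of its 40 members fell when adjusted over the list alone. KIF20A differed by -2.17 and -1.23, and HMMR by -1.29 and -1.08. Of G1/S and DNA replication, with medians of -0.22 and -0.37, 1 of 40 members fell when adjusted over the list alone, the helicase gene MCM6 at -0.89 and -1.16. Its camera adjusted p was 1.30e-07, or 0.521 with an estimated correlation. Of homologous recombination and Fanconi genes, 6 of 18 fell when adjusted over the list alone, among them BLM at -0.62 and -0.80 (medians -0.40 and -0.27, camera adjusted p = 5.50e-05, or 0.521 with an estimated correlation).

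Replication-dependent histones had medians of -0.89 in HK1 and -0.24 in HK1EBV, and 11 of 29 fell when adjusted over the list alone (camera adjusted p = 4.53e-10, or 0.521 with an estimated correlation). Their transcripts are near-identical copies, so the value of a single one, such as H3C12 at -1.86 and -0.95, is uncertain. Over windows of 9 neighbouring genes the largest median CAPE change was 0.94 in size, against at most 0.72 in 1000 permuted gene orders. Windows above the 95th percentile of the permuted maxima formed 2 stretches, both on chromosome 6. That from SLC17A4 to HFE had medians of -0.70 in HK1 and -0.21 in HK1EBV, with 9 of its 13 genes in the histone list. Its 4 other genes had a median of 0.09 for the mean change of both lines. That from ZNF391 to H2BC17 had medians of -0.89 and -0.22, with 6 of its 15 genes in the list. Besides ZNF391 and ZNF184, its other genes were histone genes outside the list, H2BC13, H2AC13, H2AC14, H2AC15, H2AC16, H4C13 and H2BC17. Heat shock and cytosolic chaperones had medians of -0.25 and -0.16 and oxidative phosphorylation of -0.13 and -0.11, with 0 of 19 and 0 of 25 members passing over the list alone. Their camera adjusted p were 0.00117 and 0.0320, both 0.521 with an estimated correlation, and the medians of oxidative phosphorylation lay among the random lists, at percentiles 3.64 and 7.01. Of 6 targets of the aryl hydrocarbon receptor, CYP1B1 and CYP1A1 fell when adjusted over the list alone, CYP1A1 at -0.34 and -1.02. The list, at a camera adjusted p = 0.0330, or 0.521 with an estimated correlation, did not pass without CYP1B1, at 0.330.

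The NRF2 and electrophile response list, of genes for detoxification and glutathione supply, had medians of 0.50 and 0.51 (camera adjusted p = 1.95e-10, or 0.521 with an estimated correlation). Of its 28 members, 16 rose when adjusted over the list alone, and SQSTM1, an autophagy receptor, was higher by 1.24 and 1.53. HMOX1, the inducible heme oxygenase, was higher by 0.40 and 0.31 and NQO1 by 0.09 and 0.30. Endoplasmic reticulum chaperones and the unfolded protein response had medians of 0.50 and 0.49, with 11 of 19 rising when adjusted over the list alone (camera adjusted p = 2.89e-09, or 0.521 with an estimated correlation). HERPUD1 was higher by 1.05 and 2.20, and DNAJB9 by 0.82 and 1.40. The list of ATF4 and amino acid stress stood at 0.24 in HK1 and 0.80 in HK1EBV (camera adjusted p = 6.27e-07, or 0.521 with an estimated correlation). Of its 28 members, 15 rose and 1 fell when adjusted over the list alone, with NUPR1 at 1.16 and 2.40 and CHAC1 at 0.72 and 1.71.

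Hypoxia and glycolysis genes were higher by a median of 0.78 in HK1 and 0.32 in HK1EBV, and 20 of 28 rose when adjusted over the list alone (camera adjusted p = 3.27e-10, or 0.521 with an estimated correlation). ENO2, a glycolytic enolase gene, was higher by 1.99 and 0.75. Of autophagy and lysosome genes, 15 of 27 rose when adjusted over the list alone (medians 0.40 and 0.33, camera adjusted p = 4.51e-10, or 0.521 with an estimated correlation), including WIPI1 at 1.22 and 1.84. Metallothioneins and the zinc response had medians of 0.31 and 0.46 (camera adjusted p = 7.31e-06, or 0.521 with an estimated correlation), and 4 of 9 members rose when adjusted over the list alone. MT1F and MT1X were higher by 1.28 and 0.98 in HK1 and by 1.18 and 1.07 in HK1EBV, again among near-identical copies. Antigen presentation had medians of 0.17 and 0.23, with 3 of 11 members rising when adjusted over the list alone (camera adjusted p = 0.0249, or 0.521 with an estimated correlation), at percentiles 95.6 and 99.4 of random lists.

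The targets of NF-κB, the factor CAPE is known to inhibit, had medians of 0.12 and 0.18 with CAPE (camera adjusted p = 0.00589, or 0.521 with an estimated correlation), at percentiles 95.7 and 99.9 of random lists, and 12 of 30 went opposite ways in the lines. Adjusted over the list alone, 5 of 30 rose and 1 fell. The chemokine gene CXCL8 was higher by 1.12 and 1.29, the feedback inhibitor TNFAIP3 by 1.06 and 1.35, and the subunit gene NFKB2 by 1.08 and 1.17. The cytokine gene IL1B differed by -1.17 and -1.43. RELA was higher by 0.31 and 0.27 and NFKBIA by 0.32 and 0.54, and NFKB1 differed by -0.06 and -0.06.

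Cholesterol synthesis genes had a median of -0.71 in HK1, at percentile 0 of random lists matched on level, and of -0.02 in HK1EBV, at percentile 40.2. The list had a camera adjusted p = 0.000231, or 0.585 with an estimated correlation, and 0 of its 18 members passed over the list alone. HMGCS1, at an early step of the pathway, differed by -2.36 and -0.46, and DHCR7, at its last step, by -1.45 and -0.04. As a list these genes stood highest on the HK1 DMSO array, at a median of 0.54 above their mean over the arrays. The medians on HK1 CAPE, HK1EBV DMSO and HK1EBV CAPE were -0.17, -0.07 and -0.12.

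**Figure D3:**
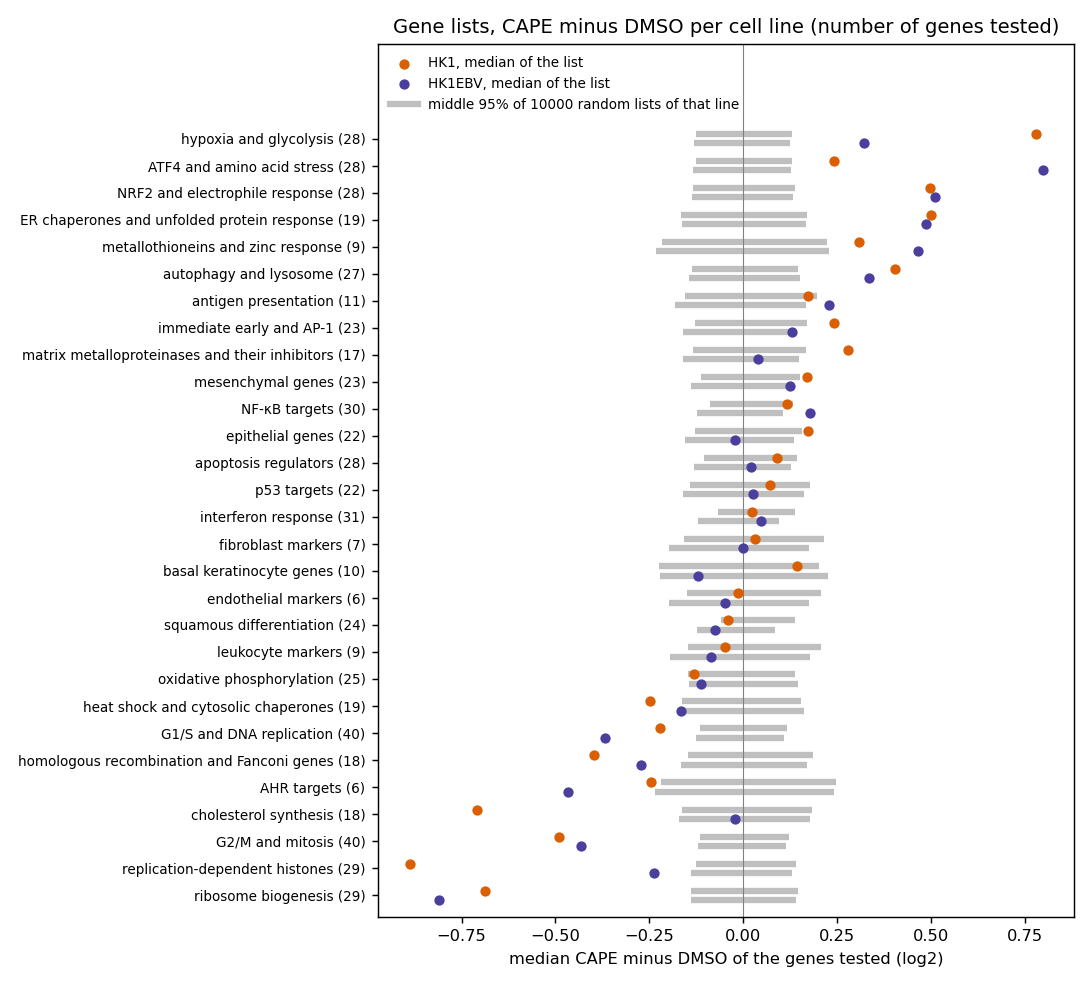
Median CAPE minus DMSO (x axis, log2) of 29 gene lists in HK1 (orange) and HK1EBV (violet), with the number of genes tested per list in parentheses and grey bars for the middle 95% of 10000 random lists matched on level. Ribosome biogenesis lies at -0.69 and -0.81, and cholesterol synthesis at -0.71 in HK1 and -0.02 in HK1EBV.

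The other 12 lists did not pass for CAPE, and 0 of their members passed over all genes with the planned setting. Without the genes of zero residual 4 p53 targets were higher and 1 lower, 3 and 3 immediate early, 3 and 1 interferon, 2 and 3 mesenchymal and 3 and 0 metalloproteinase genes. They were 2 and 1 for epithelial, 1 and 2 for basal keratinocyte, 1 and 1 for squamous, 1 and 1 for apoptosis and 1 and 0 for leukocyte genes, and 0 for fibroblast and endothelial markers. Median changes in HK1 and HK1EBV were 0.07 and 0.02 for p53 targets, where 6 of 22 rose and 1 fell when adjusted over the list alone, among them GDF15 at 0.53 and 1.33 and PLK2 at -0.76 and -1.03. Immediate early genes had 0.24 and 0.13, with 5 of 23 rising and 3 falling over the list alone, such as DUSP1 at 0.97 and 1.08 and FOSL1 at -0.62 and -0.83. The interferon response had 0.02 and 0.05, with 1 of 31 rising and 1 falling over the list alone, OAS1 at 0.71 and 1.12 and SAMD9 at -0.77 and -0.75. Mesenchymal genes had 0.17 and 0.12, with 2 of 23 rising and 3 falling over the list alone, and ITGA5 at 1.84 and 0.80 and THBS1 at -1.13 and -1.62 went opposite ways. Basal keratinocyte genes had 0.14 and -0.12, with 1 of 10 rising and 2 falling over the list alone. Among them were LAMB3 at 0.91 and 0.71 and the transcription factor gene SOX2 at -0.87 and -1.55. Epithelial genes had 0.17 and -0.02, with PRSS8 the 1 of 22 to rise over the list alone. Leukocyte markers had -0.05 and -0.09, with 1 of 9, CD68, rising over the list alone by 1.23 and 1.14.

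Over the list alone 0 members passed of 17 matrix metalloproteinases and inhibitors, 24 squamous differentiation genes, 28 apoptosis regulators, 7 fibroblast markers and 6 endothelial markers. Their medians were 0.28 and 0.04, -0.04 and -0.08, 0.09 and 0.02, 0.03 and 0.00, and -0.01 and -0.05. Leukocyte markers had a positive mean with negative medians and a negative test, and endothelial markers a positive mean and test with negative medians. For basal keratinocyte genes the mean and the test were negative and the median over both lines positive, and for apoptosis regulators it was the reverse. The cell cycle inhibitor gene CDKN1A was higher by 0.97 and 0.64, ATF3 by 1.21 and 0.80, VIM by 0.94 and 0.60 and CDH1 by 0.78 and 0.25. CCNB1 differed by -1.21 and -0.99, MKI67 by -0.53 and -0.61, MYC by -0.53 and -0.42, CCND1 by -0.28 and -0.73 and CDK1 by -0.23 and -0.17. GCLM, HSPA5, MMP2, MMP9, BCL2, BAX and EGFR differed on average by 0.67, 0.59, 0.33, 0.10, -0.10, 0.05 and 0.07. MMP9 stood at 1.47 to 1.63 and BCL2 at 1.47 to 1.67 on the arrays, under the array medians, where a fall may not show.

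The next comparison asked how HK1EBV differed from HK1 across both treatments. In HK1EBV, 200 genes were higher and 240 lower (limma with Benjamini-Hochberg adjustment, adjusted p under 0.05). On simulated data the false calls of this test were a larger share of the calls than 0.05. DNAJC15, a mitochondrial co-chaperone gene, fell, with differences of -4.41 with DMSO and -3.65 with CAPE. The mean was -4.03 ± 0.20 (moderated SE of limma, n = 2 treatments), and the SD of the 2 differences was 0.54. In HK1EBV DNAJC15 stood at 0.56 and 0.59, under the filter value of 0.997, so the size of its fall is a lower limit. GAS6, the ligand of the TAM receptors, the protease inhibitor gene SLPI and the mechanosensitive channel gene PIEZO2 fell, with means of -2.57 ± 0.11, -1.89 ± 0.11 and -1.92 ± 0.11. Higher in HK1EBV were CERS3, a ceramide synthase gene, by 2.70 ± 0.15, and S100A8, a calprotectin subunit gene, by 2.45 ± 0.14.

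Also among the genes that rose were CNTN1 by at least 2.90, as it stood at 0.67 and 0.86 in HK1 under the filter value of 0.997, SLC38A5 by 2.42, EMP3 by 2.18, NRSN2 by 2.18, CRAT by 2.10, CYBRD1 by 2.02, CLCA2 by 1.85 and PEPD by 1.79. PSTPIP2, EYA1, ADAMTS1, SYTL3, LANCL2 and TENM2 fell, with means of -2.55, -2.40, -2.22, -2.17, -2.10 and -1.94. The limma adjusted p, with Benjamini-Hochberg adjustment, lay between 0.0164 and 0.0332 for these 20 genes. DNAJC15 and GAS6 lie on chromosome 13, PIEZO2 and PSTPIP2 on chromosome 18, and LANCL2 in a stretch of chromosome 7 with other lower genes. Other stretches of lower genes ran from USP53 to NUDT6 on chromosome 4 and from RHOBTB2 to NKX2-6 on chromosome 8, with 4 genes that passed in each. Of the 440 genes, 86 lay on chromosomes 13 and 18 or in these 3 stretches, all of them lower, and without these 354 genes remained, 200 higher and 154 lower. The count was 0 without the filter on dim probe sets and 0 without treatment as a block, against 3503 genes at an unadjusted p under 0.05 in limma. It was 1756, 947 higher and 809 lower, without the 57 genes of zero residual, and with all arrays shifted to one median the split was 865 higher and 661 lower.

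Along chromosome 13 the median over 253 genes of the mean difference of both treatments was -0.42, with 47 lower and 0 higher among the genes that passed. Along chromosome 18 it was -0.37 over 205 genes, with 21 lower and 0 higher. By treatment the medians were -0.37 with DMSO and -0.29 with CAPE on chromosome 13, and -0.38 and -0.37 on chromosome 18. The stretch of chromosome 7 ran from COBL to ZNF479, with a median of -0.82 over 19 genes of which 10 passed. It held LANCL2, and the serine synthesis gene PSPH. The stretch of chromosome 4 had a median of -0.50 over 13 genes and that of chromosome 8 of -0.66 over 10. The largest window median of the line difference was 1.52 in size, against at most 0.94 in 1000 permuted gene orders.

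**Figure D4:**
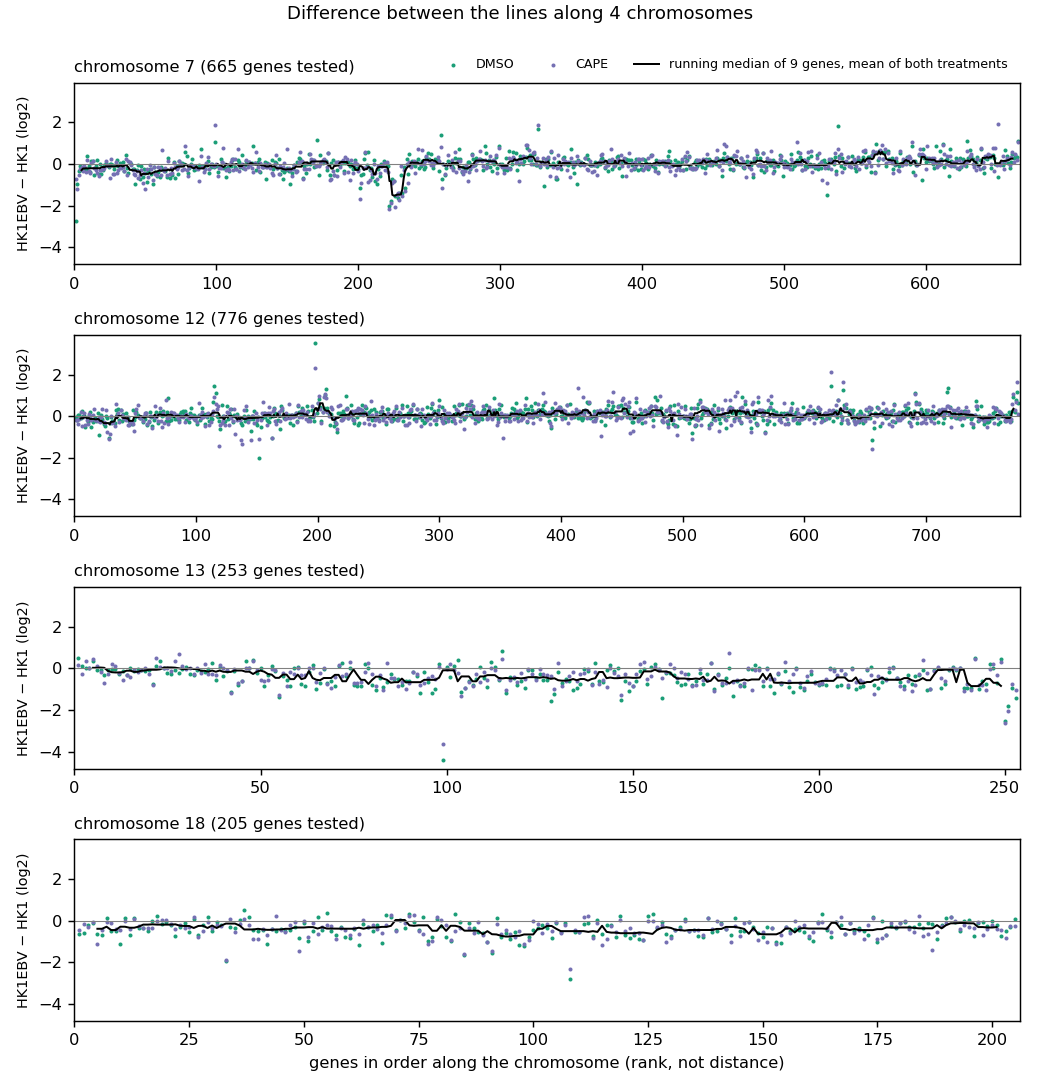
HK1EBV minus HK1 (log2, y axis) with DMSO (green points) and CAPE (violet points) for the genes tested in their order along chromosomes 7, 12, 13 and 18 (x axis, rank and not distance), with a black running median over 9 genes of the mean of both treatments. Most genes of chromosomes 13 and 18 lie below 0, with medians of -0.42 and -0.37 for the mean of both treatments, and chromosome 12 is shown for comparison.

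With DMSO alone 136 genes were at least 2-fold higher in HK1EBV and 148 lower, and with CAPE alone 141 and 171. Both treatments shared 58 higher and 83 lower, against 1.26 and 1.67 for independent lists of these sizes. With all arrays shifted to one median the split with CAPE alone became 168 higher and 150 lower. Of the 29 lists, 5 were higher and 7 lower in HK1EBV by camera with the preset correlation. None (0) passed with an estimated correlation, where the lowest adjusted p was 0.719, or by fry, where it was 0.128. Here too both rest on 1 residual degree of freedom, so hardly any list could have passed. Of the 12 lists, 10 had medians outside the middle 95% of random lists with both treatments, and ATF4 and cholesterol synthesis lay within it with CAPE, at percentiles 14.4 and 61.9. The counts of members over all genes also moved without the 57 genes of zero residual, and both are given below. Of all 15137 genes in that fit 1756 passed for the line difference, so small counts below may be no more than that share.

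Interferon response genes were higher in HK1EBV by a median of 0.50 with DMSO and 0.56 with CAPE (camera adjusted p = 7.57e-08, adjusted p = 0.719 with an estimated correlation). Of 31 members, 18 rose when adjusted over the list alone and 8 over all genes tested, or 17 without the genes of zero residual. IFI44L was higher by 1.22 and 2.42, IFIT1 by 1.24 and 2.20, USP18 by 1.29 and 1.91 and IFI6 by 1.47 and 1.68. G2/M and mitosis had medians of 0.25 and 0.29, with 14 of 40 rising and 3 falling when adjusted over the list alone and 1 and 1 over all genes, or 10 and 3 without the genes of zero residual (camera adjusted p = 0.000453). Among NRF2 targets, medians were 0.18 and 0.35, with 8 of 28 rising and 2 falling over the list alone and 2 and 1 over all genes, or 7 and 2 without those genes (camera adjusted p = 0.00591). Squamous differentiation genes had medians of 0.14 and 0.13, and 2 of 24, S100A8 and SPRR3, rose both over the list alone and over all genes, where 3 did without those genes (camera adjusted p = 0.0148). Oxidative phosphorylation had medians of 0.25 and 0.23, with 0 of 25 passing either way, but 4 higher and 1 lower over all genes without those of zero residual (camera adjusted p = 0.00957). For these 4 lists, too, the adjusted p = 0.719 with an estimated correlation.

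Lower in HK1EBV were NF-κB targets, with medians of -0.16 and -0.22 (camera adjusted p = 0.00120, adjusted p = 0.719 with an estimated correlation). Adjusted over the list alone 7 of 30 fell, and 4 did over all genes, or 8 without the genes of zero residual, among them TNFAIP2 at -1.57 and -1.70 and the urokinase gene PLAU at -1.24 and -1.53. Mesenchymal genes had medians of -0.11 and -0.27 (camera adjusted p = 0.00462, adjusted p = 0.719 with an estimated correlation). Over the list alone 8 of 23 fell and 2 rose, and over all genes 7 fell and 0 rose, or 7 and 2 without the genes of zero residual, with THBS1 at -1.13 and -1.62 and VIM at -0.90 and -1.24. Immediate early genes had medians of -0.23 and -0.40 (camera adjusted p = 0.00719, adjusted p = 0.777 with an estimated correlation). Over the list alone 10 of 23 fell and 1 rose, and over all genes 7 fell, or 10 with 1 rising without the genes of zero residual, such as HBEGF at -1.43 and -1.64. In the ATF4 list, with medians of -0.37 and -0.04 (camera adjusted p = 0.00957, adjusted p = 0.777 with an estimated correlation), 5 of 28 fell over the list alone and 4 over all genes, or 6 without the genes of zero residual. The serine synthesis genes PHGDH and PSPH were at -2.38 and -1.65 with DMSO and at -1.71 and -1.39 with CAPE, PSPH in the stretch of chromosome 7.

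Apoptosis regulators had medians of -0.13 and -0.20 (camera adjusted p = 0.0384, adjusted p = 0.777 with an estimated correlation). Over the list alone 4 of 28 fell and 1 rose, and over all genes 2 fell and 1 rose, or 5 and 1 without the genes of zero residual. The death receptor gene TNFRSF10B was at -1.03 and -1.26. Ribosome biogenesis genes had medians of -0.14 and -0.27 (camera adjusted p = 0.0114, adjusted p = 0.719 with an estimated correlation), with 7 of 29 falling and 1 rising over the list alone and 0 over all genes, or 5 and 1 without the genes of zero residual. Cholesterol synthesis had medians of -0.65 with DMSO and 0.05 with CAPE (camera adjusted p = 0.0472, adjusted p = 0.864 with an estimated correlation), and 0 of 18 passed either way, but 3 were lower over all genes without those of zero residual.

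No other list passed for the line difference. Without the genes of zero residual the members higher and lower over all genes were 3 and 1 for heat shock, 2 and 1 for endoplasmic reticulum chaperones, 3 and 4 for p53, 3 and 2 for basal keratinocyte, 3 and 1 for epithelial, 3 and 2 for autophagy, 1 and 2 for antigen presentation and 4 and 4 for metalloproteinase genes. They were 2 and 3 for G1/S, 1 and 2 for hypoxia, 1 and 0 each for homologous recombination, aryl hydrocarbon receptor, histone and leukocyte lists, and 0 for metallothioneins and fibroblast and endothelial markers. The counts that follow are those of the planned setting. Medians with DMSO and CAPE were -0.03 and 0.20 for heat shock genes, where 3 of 19 rose over the list alone and 1 over all genes, HSPB1. Endoplasmic reticulum chaperones had medians of -0.002 and 0.18, with 2 of 19 rising and 1 falling over the list alone and 1 rising over all genes. Among p53 targets, at -0.08 and -0.20, 3 of 22 rose and 3 fell over the list alone and 1 fell over all genes, TNFRSF10B. Basal keratinocyte genes had medians of 0.06 and -0.07, with 3 of 10 rising and 2 falling over the list alone. Over all genes SOX2 at 1.90 and 1.22 and KRT15 at 1.44 and 0.91 rose and LAMB3 at -0.88 and -1.08 fell. Epithelial genes had 0.15 and -0.05, with 3 of 22 rising and 1 falling over the list alone and 1 and 1 over all genes, and the protease gene PRSS8 fell, at -1.67 and -1.64. Autophagy and lysosome genes had 0.11 and 0.11, with 3 of 27 rising and 2 falling over the list alone and 2 and 1 over all genes, LAMP1 among those that fell. Antigen presentation had -0.19 and -0.15, with 1 of 11 rising and 2 falling over the list alone and 0 over all genes. Matrix metalloproteinases and inhibitors had -0.17 and -0.16, with 3 of 17 rising and 5 falling over the list alone and 1 falling over all genes, TIMP4.

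Medians were 0.10 and -0.07 for G1/S genes, 0.06 and 0.15 for homologous recombination and Fanconi genes, 0.05 and -0.35 for hypoxia and glycolysis and -0.07 and -0.05 for aryl hydrocarbon receptor targets. Metallothioneins had 0.13 and 0.18, histones -0.17 and 0.49, fibroblast markers 0.00 and -0.03 and endothelial markers 0.02 and -0.01. Of these 8 lists 0 members passed over the list alone or over all genes with the planned setting. Of leukocyte markers, at -0.09 and -0.02, CD68 was higher by 0.61 and 0.52 and rose over the list alone, with 0 over all genes. The test was negative with a positive mean for matrix metalloproteinases, leukocyte markers, endothelial markers and aryl hydrocarbon receptor targets, and for basal keratinocyte genes the test and the mean were positive with a negative median over both treatments.

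The last comparison asked where the lines differed in their CAPE change, a difference of differences from 4 single arrays without a test. In HK1EBV the change was at least 2-fold higher than in HK1 for 52 genes and lower for 65, a split that became 70 and 56 with all arrays shifted to one median. INSIG1, a regulator of sterol synthesis, differed by -1.75 in HK1 and by 0.83 in HK1EBV, and HMGCS1 by -2.36 and -0.46. FAM20C, KIF27, SELENOM and SLFN13 were the other genes with a more positive change in HK1EBV, by 2.02, 1.69, 1.55 and 1.48. NDRG1, a gene induced by hypoxia, was higher by 3.36 in HK1 and 0.63 in HK1EBV, and the collagenase gene MMP13 by 2.35 and 0.32. The other genes with a more negative change in HK1EBV were MMP12 by -1.67, HAS2 by -1.57, DGCR6 by -1.56 and IL10RB by -1.50. MMP12 stood at 0.74 and 0.69 on the HK1 arrays, under the filter value of 0.997, where a fall with CAPE could not have shown. HAS2 stood at 1.28 and 1.41 on the HK1 arrays, under the array medians, where a fall may not show. Among the lists, the median of the gene-wise differences between the lines in the CAPE change was 0.37 for ATF4 targets, 0.70 for cholesterol synthesis and 0.71 for histones, each at percentile 100 of random lists. Hypoxia and glycolysis stood at -0.49, at percentile 0, and G1/S at -0.14, at percentile 0.13. Basal keratinocyte genes stood at -0.24, at percentile 0.31, and mesenchymal genes at -0.15, at percentile 2.07.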

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

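The tests on cholesterol genes, of signal level and of the HK1 DMSO array, were chosen only after the result was seen. Of 276 results, the named genes, the leading list members of either comparison and the lists, 10 genes moved in opposite directions with CAPE in the lines, by at least 0.2 in each, and 0 lists did. The difference was not tested, since each group had 1 array. INSIG1 stood at -1.75 in HK1 and 0.83 in HK1EBV, 2.58 apart. FAM20C was 2.02 apart, at -1.49 and 0.53, and KIF27 1.69 apart, at -1.24 and 0.45. SELENOM was 1.55 apart, at -0.43 and 1.12, and SLFN13 1.48 apart, at -0.55 and 0.93. DGCR6 went the other way by -1.56, at 0.69 in HK1 and -0.87 in HK1EBV. The sterol synthesis gene SQLE was 1.24 apart, at -0.96 and 0.28, and the interferon-induced gene IFIT1 0.95 apart, at -0.52 and 0.44. The collagenase gene MMP1 differed by -0.92, at 0.53 and -0.39, and COX7B, of oxidative phosphorylation, by -0.69, at 0.43 and -0.26. INSIG1, FAM20C, KIF27, SELENOM, SLFN13 and DGCR6 had been named by the rule for the most unlike CAPE changes, which favours opposite signs. Among all 15194 genes tested 636 had opposite signs at that size.

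The 7188 probe sets without a single gene were outside the comparisons. Of these 2 were at least 2-fold higher and 4 at least 2-fold lower with CAPE in both lines, against 0.0584 and 0.0851 for independent lists.

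INSIG1 and HMGCS1 belong to the sterol genes, whose list had a median CAPE change of -0.71 in HK1 and -0.02 in HK1EBV. A trend with signal level was argued against, since the list lay at percentile 0 of random lists matched on level in HK1. The lines differed by a list median of 0.0505 with CAPE and -0.65 with DMSO. As a list median the HK1 DMSO array thus stood apart from the other 3. A hypothesis is that the state of that culture or array may account for the list median. It does not cover every member. INSIG1 stood lowest on HK1 CAPE, at 3.99, against 5.74 on HK1 DMSO, 5.10 on HK1EBV DMSO and 5.93 on HK1EBV CAPE. In the order HK1 DMSO, HK1 CAPE, HK1EBV DMSO and HK1EBV CAPE, DHCR7 stood at 8.51, 7.06, 7.85 and 7.81. HMGCS1, at 7.24, 4.88, 5.11 and 4.65, did stand apart on HK1 DMSO. A CAPE response of HK1 from a higher starting level stays open as well, untested with 1 array per group.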

How the results depend on the processing

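The fits without genes of zero residual were chosen after the result was seen. The number of CAPE genes moved from 1 to 0 without a filter, 894 with the filter at the 50th percentile, 1006 with arrays shifted to one median, 755 with quantile normalization, 12 with the mean of probe sets, 7 with a trend, 379 with a robust prior, 0 without the block and 544 at an adjusted p under 0.10. The line count moved from 440 to 0 without a filter, 1296, 1526 (865 higher and 661 lower, against 200 and 240), 1324, 959 with a robust prior, 0 without the block and 1390 at 0.10. At an unadjusted p under 0.05 limma gave 2968 and 3503 genes. CYP1B1 had an adjusted p between 4.16e-06 and 0.245 over these alternatives.

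A candidate explanation is the 57 genes with a residual of exactly 0, which lower the prior degrees of freedom (3.90). Of these 40 had one value on all 4 arrays, and 12 lay above the 50th percentile filter. Without them these were 9.89, with 1243 CAPE genes and 1756 line genes. A level difference between arrays was argued against, since shifting the medians as well gave 1020. Leaving genes out by their residual selects on the outcome, so 1243 may be too high. Genes of zero residual numbered 150 without a filter, 12 at the 50th percentile, 0 with medians shifted and 1 with quantile normalization. CAPE genes in these settings were 0, 894, 1006 and 755. Shifting and quantile normalization left out no gene by its residual. The robust prior kept all 57 and gave 379.

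At 1.5-fold the counts were 1089 in HK1, 1145 in HK1EBV, 442 in both lines, 1271 for the lines with DMSO, 1539 with CAPE and 957 for the difference in CAPE change. At 3-fold they were 31, 29, 7, 60, 76 and 7. With arrays shifted to one median the difference in CAPE change split into 70 higher and 56 lower, against 52 and 65. The line difference with CAPE then split into 168 higher and 150 lower, against 141 and 171. The correlation was 0.549 by Pearson and 0.442 by Spearman. Of the lists called, 17 for CAPE and 12 for the line, 0 and 0 passed with an estimated correlation and 0 and 0 by fry. Both of these rest on 1 residual degree of freedom, so hardly any list could have passed. The cause of the other moves was not tested. Of the named genes' other values 1659 kept direction and side of the threshold, 489 newly passed and 115 no longer passed, and of lists 233 and 0 and 60, with 0 reversed.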

Other observations

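All tests of the chromosome pattern except that on gene families were chosen after the result was seen. SLPI, a secreted protease inhibitor gene, fell in HK1EBV, at -1.86 with DMSO and -1.93 with CAPE, and was higher with CAPE by 1.22 in HK1 and 1.15 in HK1EBV. The macrophage-associated lysosomal gene CD68 was higher with CAPE by 1.23 and 1.14 while the other leukocyte markers and CD68 together had a median of -0.05 and -0.09. The amelotin gene AMTN, higher with CAPE by 1.67 and 1.68, fell in HK1EBV, at -1.58 and -1.57. NFKB1, the gene of an NF-κB subunit, fell in HK1EBV, at -0.72 and -0.71, and with CAPE stood at -0.06 and -0.06.

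The line differences ran along chromosomes. Of neighbouring genes that passed, 44 pairs had one direction, against at most 14 in 1000 permuted gene orders, which argues against accident of placement. Shared probes within gene families were argued against as well, since 9 of the 44 pairs had symbols with the same first 3 letters. Genes that did not pass had a median of -0.19 on chromosome 13 and -0.33 on chromosome 18, against -0.0989 to 0.0966 on the others, so a hypothesis is that the lines may differ in copy number there. No DNA was measured, and the virus and the separate history of the lines could not be separated here.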
